A study of Mus musculus with 8 samples.

How the data were processed

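Polyadenylated RNA of sorted GFP-positive and GFP-negative cells from 4 mouse alveolar organoid lines was sequenced, 1 library per sort and line, 8 libraries in all. According to the labels, organoids were grown in 90% matrigel, and libraries were made from 300 ng of RNA with 14 cycles of PCR. The values are raw read counts per gene symbol, deposited by the authors as whole numbers, 1 column per library and without normalization. The authors' processing notes name cutadapt 1.16, STAR 2.5.3a, featureCounts and Subread and the genome build mm9; the annotation, the strandedness and the treatment of reads that map to several places are not given in the sources used here. Overlapping and antisense genes therefore cannot be told apart, and near-identical genes such as Lyz1 and Lyz2, or Hspa1a and Hspa1b, can share reads. Because the reference annotation used here is of another build than mm9, it served only to match names, and no coordinates are printed.

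The table held 23284 genes, 5616 of them with 0 counts in every library. Of their symbols, 20683 are current, 2359 are older synonyms and 242 matched no gene in the reference. Genes are named as in the table, with the current symbol beside 1810011O10Rik (Tcim) and 1700009P17Rik (Cfap126); Nov is now Ccn3. Total counts were 5910344 to 16032633 per library. Counts of PCR products without molecular identifiers are not independent molecules.

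GFP-positive libraries were compared with GFP-negative ones in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (10 counts scaled to library size in at least 4 libraries and 15 in total), which left 12848. Counts were scaled by TMM factors, fitted with the sort as the only term, and tested with the robust two-sided quasi-likelihood test. Values of p were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an FDR of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.154, and 0.0897 with line as a term. For Sftpc the exact two-sided permutation and sign-flip tests of log2 CPM were run as well. Log2 CPM for principal components and sums of squares used a prior count of 2.

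Before the data were examined, 35 gene lists were fixed from general knowledge of lung cell types and pathways, as were the tests, the rule for named genes and the alternatives, except where stated. Of these, 33 had at least 3 measured members and were tested together with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 33. The macrophage and leukocyte list had 2 measured members, and the list of Y-linked genes and Xist served as a check of the lines. A member was counted as risen or fallen at the FDR over all genes tested, and the count adjusted over the list alone stands beside it. Some lists share members, such as 4 genes between the AT2 and the lipid synthesis list and 3 between the AT2 list and the list of lysosome and lamellar body genes. Named are Sftpc, the 10 genes with the highest and the 10 with the lowest log2 fold change among those called with a mean log2 CPM of 3 or more and the same direction in 4 lines, and up to 4 members of each list with the smallest p. Members outside this rule are marked as named after their values were seen, apart from those listed as shared between lists or as copies of another gene; Lyz1 was also chosen that way.

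The libraries were paired by line. After removal of the group means, the 2 libraries of a line correlated across genes at r = 0.37, 0.46, 0.32 and 0.40 for lines SN2285, SN2286, SN2293 and SN2294, and libraries of different lines at −0.003 or lower; genes are not independent replicates. A paired fit with line as a term (replicate block) gave 6169 calls, 5220 of them shared with the 5231 of the unpaired fit. Its value stands beside a result where it changes the call or moves a count by more than 1.5 times.

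The test was checked on simulated counts with the depths and dispersions of these libraries, 12848 genes and 50 changed genes per fold. It recovered 64% of the genes changed 1.5-fold, 80% of those changed 2-fold, 94% of those changed 4-fold and 100% of those changed 8-fold, with 8 false calls among 12648 unchanged genes. Few genes were changed, in equal number up and down, and no line effect was simulated. In the real libraries 5231 genes were called. The check therefore does not cover a large shift in composition or the pairing by line. A simulated list of 30 genes raised 2-fold was called by camera, and 1 of 100 random lists passed at an unadjusted 0.05. Genes were drawn independently of each other here, so this does not show how often camera calls lists whose members vary together. In the real libraries the estimated correlation ran from 0.0012 (lipid synthesis) to 0.67 (MHC class II presentation) among the called lists.

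The alternatives were line as a term, DESeq2 size factors, upper quartile scaling, library size alone, no filter, a stricter filter (10 counts and 1 CPM in at least 4 libraries), DESeq2 1.42.0 with and without line, limma-voom, a fit without robust dispersion, each library left out, and each line left out with line as a term. For the lists, camera with an estimated correlation, the rotation test fry and camera with line as a term were added. Thinning of all libraries to the depth of the shallowest was chosen after seeing the data. No library was left out of the comparison itself.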

Results

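Gene expression was measured by sequencing of polyadenylated RNA in mouse alveolar organoids, cultures of mouse lung cells grown in matrigel. The cells came from mice carrying an Sftpc-eGFP transgene, which places enhanced green fluorescent protein (GFP) under the control of the gene for surfactant protein C, a product of alveolar type 2 (AT2) cells. Each of 4 organoid lines (SN2285, SN2286, SN2293 and SN2294) was divided by fluorescence-activated sorting into GFP-positive and GFP-negative cells, which gave 4 libraries per group. The labels do not say whether each line came from its own animal. The stated purpose was to profile gene expression in the GFP-positive against the GFP-negative cells. Total counts ran from 11202576 to 16032633 in the GFP-positive libraries. They were 14408203, 14567266 and 15583384 in the GFP-negative libraries of lines SN2285, SN2286 and SN2293, and 5910344 in that of line SN2294. In all values below, a positive log2 fold change means a higher level in GFP-positive cells, n = 4 libraries per group, and levels are counts scaled to the library total with a composition factor (CPM) ± SD.

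The GFP-positive cells carried surfactant, lipid synthesis and other AT2 transcripts at high levels. The GFP-negative cells carried basal cell, fibroblast and Notch pathway transcripts and some of club and secretory cells. Sftpc stood at 17652 ± 2121 CPM in GFP-positive and 871 ± 416 CPM in GFP-negative libraries, a 20.3-fold difference (log2 fold change 4.34, SE 0.41, adjusted p = 1.3e-04, edgeR). The gap ran the other way for the basal cell regulator Trp63, at 3.6 ± 1.54 CPM in GFP-positive and 189 ± 9.8 CPM in GFP-negative libraries, 53-fold lower in the GFP-positive cells (log2 fold change −5.73, SE 0.20, adjusted p = 2.3e-08). Of 12848 genes tested, 5231 passed a false discovery rate (FDR) of 0.05, 2430 of them higher and 2801 lower in GFP-positive cells. Of these, 1988 differed at least 2-fold, 566 higher and 1422 lower. A difference of 16-fold or more was found for 13 genes higher and 391 genes lower in GFP-positive cells. All 4 lines shared the direction for 5174 of the 5231 genes, and 3 lines did for the other 57. Without the GFP-negative library of line SN2294, the shallowest, 5135 genes passed, 2055 of them at least 2-fold. Scaling by library size alone, without a composition factor, shifted the median log2 fold change of all genes from −0.01 to −0.16. The calls then became 1505 higher and 4199 lower, so that 26.4% were higher in place of 46.5%.

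**Figure D1:**
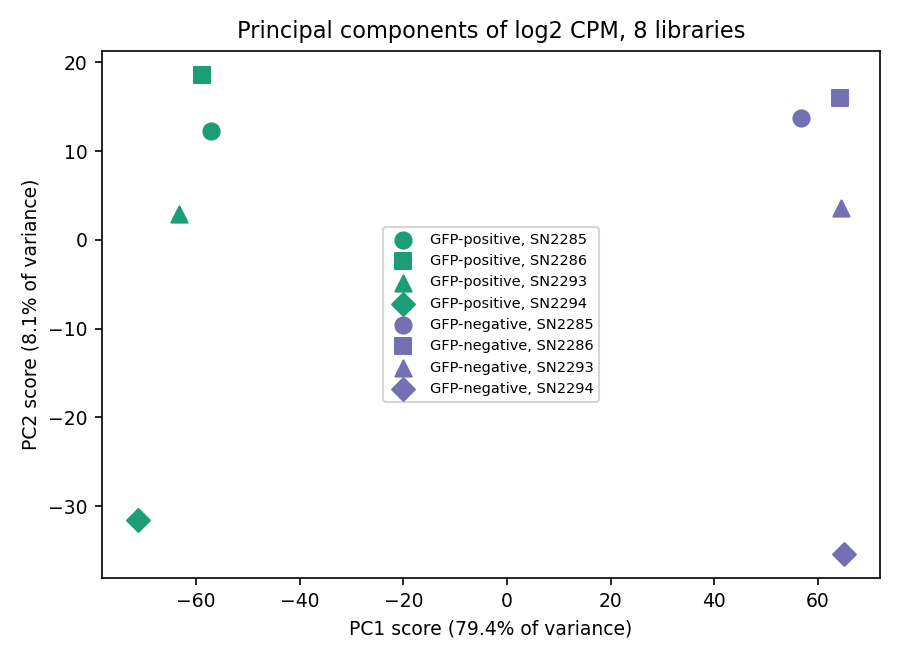
Principal components of log2 CPM over 12848 genes, with the first component (79.4% of variance) on the x axis and the second (8.1%) on the y axis. Each point is a library, green for GFP-positive and purple for GFP-negative, with a marker shape per line; the first component parts the sorts, with every GFP-positive library at a score of −57.2 or below and every GFP-negative library at 56.7 or above, and both libraries of line SN2294 lie lowest on the second.

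The sort accounted for 79.0% of the sum of squares of log2 CPM, the line for 14.6% and the remainder for 6.37%. Sftpc made up 1.42 to 1.83% of all counts in GFP-positive libraries and 0.0458 to 0.132% in GFP-negative ones. Its log2 CPM was higher in the GFP-positive library of all 4 lines, and no other division of the 8 libraries gave a larger gap (two-sided exact permutation p = 0.0286 over 70 assignments, the smallest possible). The exact sign-flip test over the 4 lines gave p = 0.125, the smallest it can reach. The cells were sorted on a reporter under the control of Sftpc, so a difference in this gene was built into the groups. The Sftpc tests are therefore only a check of the sort labels. The table of counts has no row for the GFP transcript itself.

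The list of AT2 identity genes was higher in GFP-positive cells, with 25 of its 30 members rising and 3 falling (25 and 3 adjusted over the list alone). The set test on this list gave adjusted p = 1.5e-15, and adjusted p = 0.057 with an estimated correlation. Its members with the smallest p were Lpcat1, a phospholipid acyltransferase of surfactant synthesis (log2 fold change 2.62, SE 0.09, adjusted p = 3.0e-09), Ppp1r14c (log2 fold change 3.79, SE 0.14, adjusted p = 4.6e-09), Dram1 (log2 fold change 2.30, SE 0.09, adjusted p = 6.1e-09) and the chemokine gene Cxcl15 (log2 fold change 3.52, SE 0.14, adjusted p = 1.2e-08). Other members rose as well, among them the phosphate transporter gene Slc34a2, at 4020 ± 178 CPM against 289 ± 97.3 CPM, and the lamellar body gene Lamp3, at 2664 ± 312 CPM against 623 ± 60.1 CPM. The 3 members that fell were named after their values were seen. They were the lysozyme gene Lyz2 (log2 fold change −2.39), the alarmin gene Il33 (−2.23) and the lysolipid transporter gene Mfsd2a (−2.74). Lyz2 and its near-identical neighbour Lyz1, at log2 fold change 2.06 without passing the test (adjusted p = 0.20), can share reads, so both values are uncertain. The GFP-negative libraries were not free of AT2 transcripts. Sftpc there stood at 6.59%, 2.54%, 3.07% and 7.98% of its GFP-positive level in lines SN2285, SN2286, SN2293 and SN2294, and the median of the 24 other members that rose stood between 15.4% (line SN2286) and 19.4% (line SN2294).

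**Figure D2:**
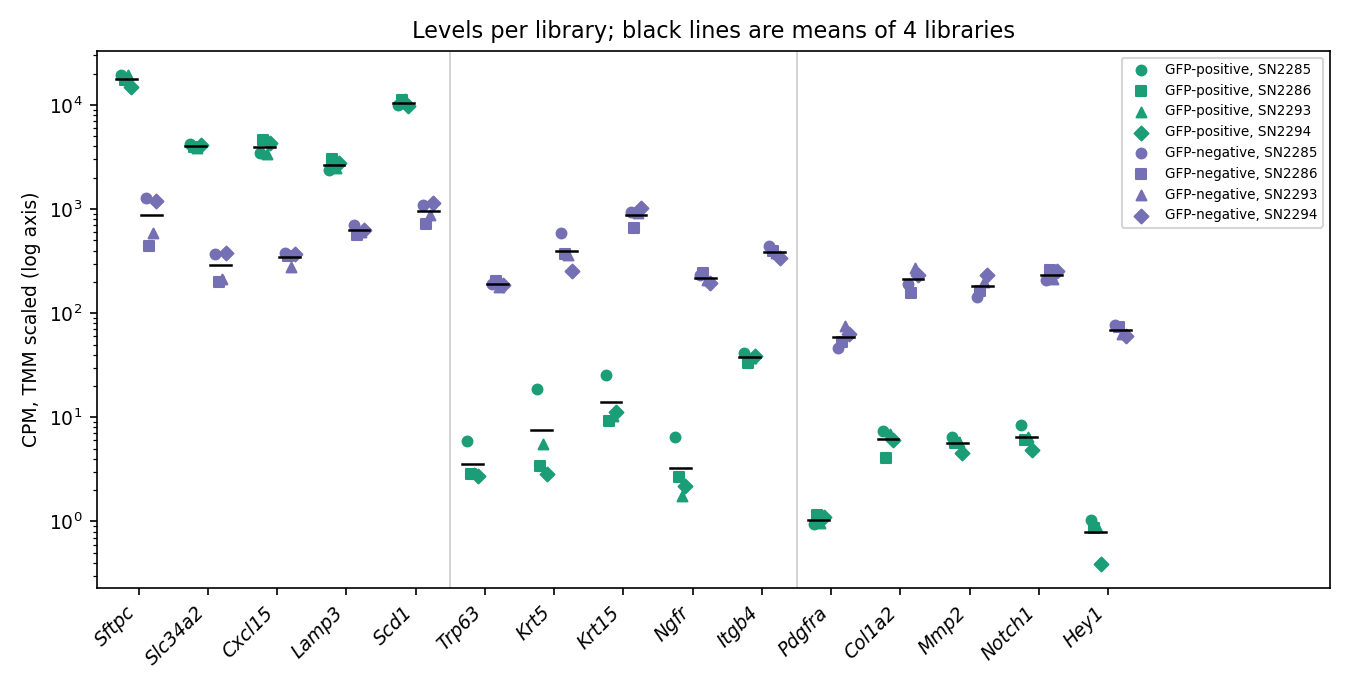
TMM-scaled CPM, on a log axis, of 15 genes in each of the 8 libraries, with GFP-positive libraries in green, GFP-negative in purple, a marker shape per line and a black line at the mean of 4 libraries. The AT2 and lipid genes at the left lie higher in GFP-positive libraries (Scd1 at 10545 ± 736 against 957 ± 196 CPM), and the basal genes in the middle and the mesenchymal and Notch genes at the right lie higher in GFP-negative ones (Krt15 at 14.1 ± 7.79 against 886 ± 163 CPM).

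Genes of fatty acid and surfactant lipid synthesis rose in GFP-positive cells. Of 28 measured members, 21 rose and 2 fell (21 and 3 adjusted over the list alone), and the list passed the set test (adjusted p = 1.8e-08; adjusted p = 0.018 with an estimated correlation). The stearoyl-CoA desaturase gene Scd1 was 11-fold higher (log2 fold change 3.46, SE 0.14, adjusted p = 2.3e-08), the lamellar body lipid transporter gene Abca3 3.89-fold (log2 fold change 1.96, SE 0.09, adjusted p = 2.0e-08) and the fatty acid synthase gene Fasn 3.52-fold (log2 fold change 1.81, SE 0.09, adjusted p = 2.8e-08). Of the list, 4 members (Abca3, Lpcat1, Scd1 and Elovl1) also stood in the AT2 list. The 2 members that fell, named after their values were seen, were the elongase gene Elovl6 (−1.56) and the lipin gene Lpin1 (−0.62). Sterol biosynthesis genes rose by smaller amounts, 15 of 24 measured members rising and 2 falling (15 and 2 adjusted over the list alone; set test adjusted p = 4.2e-04; adjusted p = 0.42 with an estimated correlation). The largest of these changes among the named members was that of Ebp, a sterol isomerase gene (log2 fold change 1.04, SE 0.10, adjusted p = 4.7e-06), followed by Mvd (0.87), Lss (0.81) and Pmvk (0.80). With scaling by library size alone 10 sterol members rose and 3 fell.

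Ranked by fold, the 10 genes highest in GFP-positive cells were Cd177, Hdc, Sftpc, Atp13a4, Lgi3, Lrg1, Esam, Slc34a2, Ppp1r14c and Slc26a4. Cd177, known as a neutrophil surface glycoprotein gene, was at 295 ± 62.9 CPM against 11.7 ± 6.31 CPM (log2 fold change 4.70, SE 0.51, adjusted p = 3.6e-04). Hdc, which encodes the enzyme that makes histamine, was at 118 ± 45.5 CPM against 6.0 ± 4.94 CPM (log2 fold change 4.51, SE 0.55, adjusted p = 6.4e-04). Lgi3 was at 863 ± 111 CPM against 58 ± 22.6 CPM, and Slc26a4, the anion exchanger pendrin, at 322 ± 65.4 CPM against 24.2 ± 11.8 CPM. The 10 lowest in GFP-positive cells were 1810011O10Rik (now Tcim), Gpnmb, Ngfr, Aqp3, Krt15, Arhgdib, Pdgfra, Upk1b, Trp63 and Krt5. Ngfr, a receptor carried by airway basal cells, was at 3.27 ± 2.14 CPM in GFP-positive and 220 ± 23.2 CPM in GFP-negative libraries (log2 fold change −6.09, SE 0.34, adjusted p = 3.7e-06), and 1810011O10Rik at 1.57 ± 0.622 and 106 ± 19.5 CPM (log2 fold change −6.12, SE 0.26, adjusted p = 1.1e-07). Gpnmb, a lysosomal glycoprotein gene, varied between lines. Its GFP-negative level was 38.6, 44.3 and 74.0 CPM in lines SN2285, SN2286 and SN2293 and 404 CPM in line SN2294, the library that also held leukocyte transcripts. Its log2 fold change went from −6.11 (SE 1.18) with all libraries to −4.72 without that library, and the call held (adjusted p = 1.0e-05).

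Basal cell genes fell in GFP-positive cells, with 14 of 16 measured members falling and 1 rising (1 and 14 adjusted over the list alone; set test adjusted p = 1.7e-08; adjusted p = 0.13 with an estimated correlation). The median log2 fold change of the list was −5.28. The keratin gene Krt5 was 52.3-fold lower (log2 fold change −5.71, SE 0.70, adjusted p = 7.5e-04), the integrin gene Itgb4 10.3-fold (log2 fold change −3.37, SE 0.10, adjusted p = 1.6e-09), the cadherin gene Cdh3 5.45-fold (log2 fold change −2.45, SE 0.11, adjusted p = 2.1e-08), and Sox15 was at 0.313 ± 0.165 against 10.1 ± 2.06 CPM (log2 fold change −5.03, SE 0.32, adjusted p = 2.6e-07). Bcam, a laminin receptor gene named after its value was seen, rose (log2 fold change 1.33, SE 0.11, adjusted p = 2.5e-06). Without the GFP-positive library of line SN2285 the log2 fold change of Krt5 was −6.64. Most basal members that fell were still present at a low level in GFP-positive libraries. The median ratio of the 14 members that fell, GFP-positive to GFP-negative, was 3.80% in line SN2285 and 1.62%, 1.54% and 1.34% in lines SN2286, SN2293 and SN2294. Some stood higher over the lines, with Cdh3 at 14.5 to 23.0%, Itgb4 at 8.40 to 11.5% and Lamb3, named after its value was seen, at 52.8 to 89.5%.

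All 14 measured genes of the fibroblast and smooth muscle list fell in GFP-positive cells (0 and 14 adjusted over the list alone; set test adjusted p = 1.9e-08; adjusted p = 0.19 with an estimated correlation). The platelet-derived growth factor receptor genes Pdgfra (log2 fold change −5.81, SE 0.20, adjusted p = 3.0e-09) and Pdgfrb (−4.44) and the collagen genes Col1a2 (log2 fold change −5.11, SE 0.23, adjusted p = 3.6e-07) and Col6a3 (−4.65) were among them. In GFP-negative cells these 4 genes stood at 59.1 ± 12.5, 27 ± 6.05, 213 ± 49.9 and 28.6 ± 7.9 CPM. The list of epithelial to mesenchymal transition genes fell alongside, 17 of 18 members falling and 1 rising (1 and 17 adjusted over the list alone; set test adjusted p = 6.8e-08; adjusted p = 0.25 with an estimated correlation). It included the matrix metalloproteinase gene Mmp2 (log2 fold change −5.03, SE 0.18, adjusted p = 1.7e-08), the repressor genes Snai2 (log2 fold change −5.23, SE 0.25, adjusted p = 3.2e-08) and Zeb2 (−5.08) and the integrin gene Itga5 (−3.57), several of which fibroblasts express. The member that rose, named after its value was seen, was the N-cadherin gene Cdh2 (0.34), which did not pass with scaling by library size alone. Among 20 TGF-beta and matrix response genes, some of which fibroblasts express, 3 rose and 10 fell (4 and 10 adjusted over the list alone). With line as a term, 5 rose and 11 fell. That list did not pass the set test (adjusted p = 0.13). Ltbp2 (−4.46), Tgfbi (−5.24) and Pmepa1 (−1.46) were lower in GFP-positive cells, and without the GFP-positive library of line SN2285 Tgfbi was at −5.94.

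The Notch pathway list fell in GFP-positive cells, 10 of 11 measured members falling and none rising (0 and 10 adjusted over the list alone; set test adjusted p = 5.3e-06; adjusted p = 0.13 with an estimated correlation). The receptor gene Notch1 was 36.2-fold lower (log2 fold change −5.18, SE 0.16, adjusted p = 3.0e-09), and the targets Hey1 (log2 fold change −6.47, SE 0.20, adjusted p = 1.8e-09), Hes1 (log2 fold change −1.61, SE 0.12, adjusted p = 8.1e-07) and Nrarp (−1.62) were lower too. Targets of p53 were lower in GFP-positive cells, 17 of 22 falling and none rising (0 and 17 adjusted over the list alone), and this list passed the set test in both forms (adjusted p = 2.1e-07; adjusted p = 0.019 with an estimated correlation). Perp, a p63 and p53 target that encodes a desmosome-associated protein, changed most among the named members (log2 fold change −3.87, SE 0.12, adjusted p = 1.6e-09), followed by Pmaip1 (−3.10), Trp53inp1 (−1.84) and Phlda3 (−1.69). The list of Wnt targets had 8 members falling and 2 rising of 14 (2 and 8 adjusted over the list alone), with Apcdd1 (−3.40), Tcf7 (−1.20) and Cd44 (−0.72) lower and Bmp4 (1.48) higher. Its set test gave adjusted p = 0.045, which was lost with line as a term (adjusted p = 0.052), with scaling by library size alone (0.10), without line SN2294 in a fit with line as a term (0.058), after thinning to a common depth (0.066) and with an estimated correlation (adjusted p = 0.32 with an estimated correlation).

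**Figure D3:**
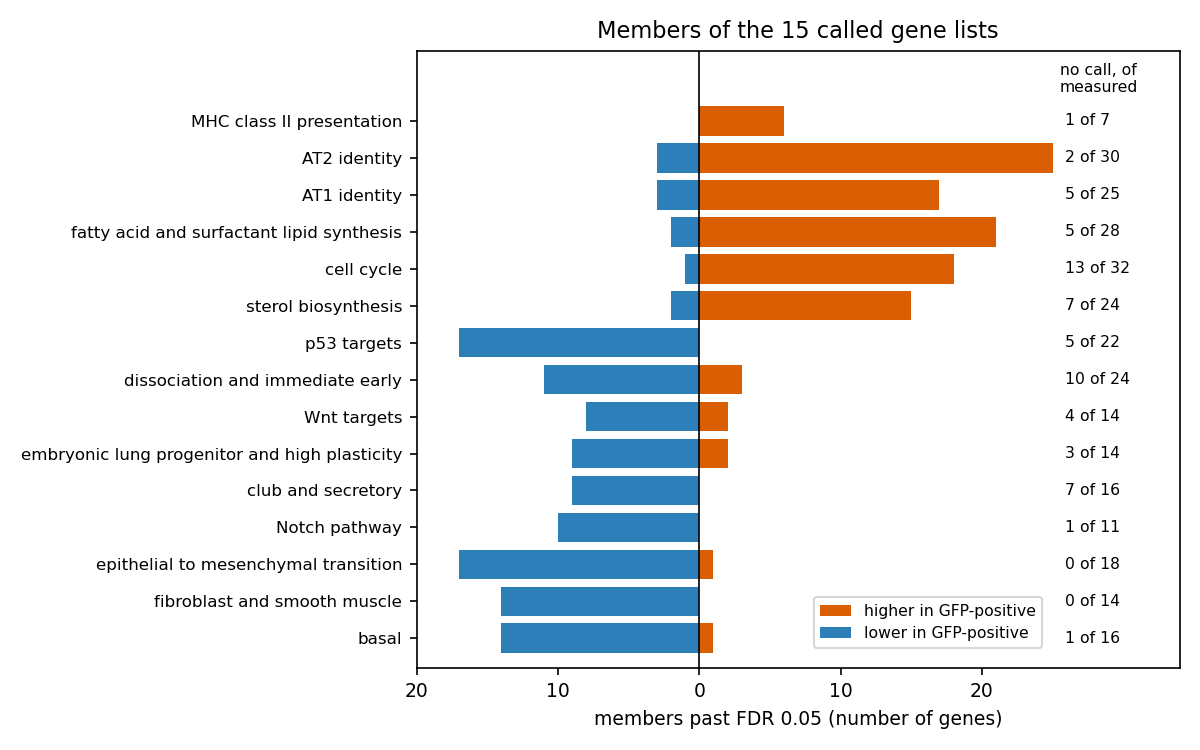
Number of members past FDR 0.05 in each of the 15 gene lists called by the set test, with those higher in GFP-positive cells to the right (orange), those lower to the left (blue) and, in the column at the right, the measured members without a call. The 6 lists at the top were called higher and the 9 below lower. For example, 25 members rose in the AT2 list and 14 fell in the basal list.

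Club and secretory cell genes were lower in GFP-positive cells for 9 of 16 measured members, with none rising (0 and 9 adjusted over the list alone; set test adjusted p = 8.0e-05; adjusted p = 0.43 with an estimated correlation). These included the haptoglobin gene Hp (log2 fold change −3.83, SE 0.27, adjusted p = 1.1e-05), the glutathione transferase gene Gsta4 (log2 fold change −1.98, SE 0.10, adjusted p = 4.1e-08) and the lactate dehydrogenase gene Ldhb (−0.94). Lypd2 was at 0.108 ± 0.108 CPM in GFP-positive and 8.07 ± 1.73 CPM in GFP-negative libraries (log2 fold change −6.18, and −7.01 without the GFP-positive library of line SN2285). The club cell secretoglobin gene Scgb1a1, named after its value was seen, did not pass the test (1.83, adjusted p = 0.19). It was among 7 measured members without a call. Cyp2f2 and Cbr2, also named after their values were seen, were far lower in GFP-positive libraries. In raw counts Cyp2f2 stood at 119 to 336 in GFP-positive and 3219 to 12756 in GFP-negative libraries, and Cbr2 at 19 to 97 and 777 to 5144. Of 14 measured genes of embryonic lung progenitors and high-plasticity cells, 9 fell and 2 rose (2 and 9 adjusted over the list alone; set test adjusted p = 0.018; adjusted p = 0.19 with an estimated correlation). Hmga2 (−1.91), Plac8 (−5.41) and Etv4 (−0.82) were lower and Id2 (1.98) was higher. This list lost its call with scaling by library size alone (adjusted p = 0.10).

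Genes of the AT1 identity list, markers of the flat gas-exchange cells, were higher in GFP-positive cells for 17 of 25 measured members and lower for 3 (18 and 3 adjusted over the list alone; set test adjusted p = 0.0014; adjusted p = 0.62 with an estimated correlation). Gprc5a (log2 fold change 1.69, SE 0.13, adjusted p = 1.2e-06), Tspan8 (1.04) and Lmo7 (0.99) rose and the podoplanin gene Pdpn fell (log2 fold change −1.94, SE 0.16, adjusted p = 5.5e-06). Ager, which encodes an abundant receptor of AT1 cells and was named after its value was seen, stood at 137 ± 74.6 CPM against 15 ± 7.44 CPM (adjusted p = 0.0044). Genes of MHC class II presentation rose for 6 of 7 measured members, with none falling (7 and 0 adjusted over the list alone; set test adjusted p = 1.8e-04; adjusted p = 0.34 with an estimated correlation). They included the invariant chain gene Cd74, at 353 ± 57.4 against 61.8 ± 19.2 CPM (log2 fold change 2.51, SE 0.25, adjusted p = 9.8e-05), the transactivator gene Ciita (2.94), H2-DMb1 (2.73) and H2-Aa (3.91).

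Cell cycle genes were slightly higher in GFP-positive cells, 18 of 32 rising and 1 falling (20 and 1 adjusted over the list alone; set test adjusted p = 2.7e-05; adjusted p = 0.60 with an estimated correlation). The transcription factor genes Foxm1 (log2 fold change 0.56, SE 0.10, adjusted p = 5.8e-04) and E2f1 (log2 fold change 0.58, SE 0.10, adjusted p = 6.0e-04) and the replication genes Mcm6 (0.50) and Pcna (0.40) rose by less than 2-fold. With scaling by library size alone 10 members rose and 1 fell. Of 24 dissociation and immediate early genes, which respond to handling and stress, 11 fell and 3 rose (3 and 13 adjusted over the list alone; set test adjusted p = 0.0048; adjusted p = 0.69 with an estimated correlation). With line as a term 19 fell and 3 rose. Hspa1b (−1.32), which can share reads with its near-identical copy Hspa1a, Ier2 (−0.72) and Ier3 (−0.68) were lower and the chaperone gene Hsp90aa1 (0.58) was higher in GFP-positive cells.

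Among 18 measured lung and foregut transcription factors, 10 rose and 6 fell (10 and 6 adjusted over the list alone). Id2 (log2 fold change 1.98, SE 0.09, adjusted p = 2.3e-08), Elf5 (log2 fold change 1.82, SE 0.09, adjusted p = 5.3e-08) and Foxp2 (log2 fold change 1.38, SE 0.08, adjusted p = 1.9e-07) rose and Foxa1 fell (log2 fold change −1.64, SE 0.09, adjusted p = 8.1e-08). As a list they did not pass the set test (adjusted p = 0.076), although they did without the GFP-positive library of line SN2293 (adjusted p = 0.044) or the GFP-negative library of line SN2294 (adjusted p = 0.045). Outside the naming rule, and named after their values were seen, the lung regulator gene Nkx2-1 rose (log2 fold change 1.25, SE 0.11, adjusted p = 3.7e-06) and the airway regulator gene Sox2 fell (log2 fold change −4.49, SE 0.53, adjusted p = 5.0e-04). Genes of the alveolar transitional state, which marks cells between AT2 and AT1 identity, went both ways, 11 rising and 7 falling among 26 (12 and 8 adjusted over the list alone; set test adjusted p = 0.43). The median log2 fold change of this list was 0.13 and its mean −0.04. Sfn (−1.28) and Fhl2 (−1.62) were lower and the keratin gene Krt8 (0.56) and the clusterin gene Clu (0.97) were higher in GFP-positive cells. With scaling by library size alone 6 rose and 8 fell.

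Interferon response genes varied in level between lines. Of 25 members 1 fell and none rose (0 and 0 adjusted over the list alone; set test adjusted p = 0.13), whereas with line as a term 18 fell and 3 rose (adjusted p = 0.0038). With an estimated correlation (0.94) and no line term, the set test gave adjusted p = 0.88. The mean log2 CPM of the list ran from 3.37 in line SN2294 to 5.73 in line SN2286 among GFP-positive libraries, and from 4.33 to 6.17 for the same lines among GFP-negative ones. Mx1 was at log2 fold change −2.27 (adjusted p = 0.067; 0.026 with line as a term), Ifi27l2a at −2.86 (adjusted p = 0.060; 5.9e-06 with line as a term) and Gbp3 at −1.56 (adjusted p = 0.12; 6.2e-07 with line as a term). Each of these passed without 1 library: Mx1 without the GFP-positive library of line SN2286 (0.019) or SN2294 (0.049), Ifi27l2a without the GFP-negative library of line SN2294 (0.019) and Gbp3 without the GFP-positive library of line SN2286 (0.030). Without the GFP-positive library of line SN2286 the log2 fold change was −3.17 for Mx1 and −2.25 for Gbp3, and without the GFP-negative library of that line it was −2.21 for Ifi27l2a (adjusted p = 0.14). The 1 member that fell was Cxcl10 (log2 fold change −0.99, SE 0.32, adjusted p = 0.040), a call lost when any of 6 libraries was left out, with adjusted p from 0.059 to 0.11; the exceptions were the GFP-positive library of line SN2286 and the GFP-negative library of line SN2294. The list passed the set test without the GFP-positive library of line SN2286 (adjusted p = 0.017) or the GFP-negative library of line SN2294 (adjusted p = 0.022). Hypoxia and glycolysis genes also gained with line as a term, from 5 rising and 1 falling of 22 (4 and 1 adjusted over the list alone; set test adjusted p = 0.083) to 12 rising and 3 falling (adjusted p = 0.0038). For this list the set test with an estimated correlation (0.79) and no line term gave adjusted p = 0.88. Ldha (0.81), Hk2 (0.98) and Gapdh (0.74) rose. The 1 member that fell, Adm (log2 fold change −3.05, SE 0.77, adjusted p = 0.019), lost its call without the GFP-positive library of line SN2285 (adjusted p = 0.057) or the GFP-negative library of line SN2286 (0.052) or SN2293 (0.051), and its log2 fold change was −3.69 without the GFP-positive library of line SN2293. The list passed without the GFP-positive library of line SN2294 (adjusted p = 0.0039) or the GFP-negative library of line SN2285 (0.028) or SN2293 (0.026).

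Markers of other cell types were mostly scarce. Of 26 macrophage and leukocyte genes in the table, 2 were measured above the filter and no set test was run. Cd68 was at 14.7 ± 3.66 CPM in GFP-positive and 30.6 ± 12 CPM in GFP-negative libraries (log2 fold change −1.04, SE 0.29, adjusted p = 0.019), a call lost without the GFP-positive library of line SN2286 (adjusted p = 0.057) or SN2294 (0.059). Coro1a did not pass (−1.16, adjusted p = 0.41; 0.65, adjusted p = 0.19, without the GFP-negative library of line SN2294). In raw counts the GFP-negative library of line SN2294 held 26 of Ptprc, 69 of Csf1r and 99 of Mrc1, leukocyte and macrophage genes, against at most 1, 2 and 4 in any other library. Ciliated cell genes were measured for 5 of 16 and Foxj1 alone passed the test, falling in GFP-positive cells (log2 fold change −3.33, SE 0.80, adjusted p = 0.0094; set test adjusted p = 0.46). Without the GFP-negative library of line SN2285, Tppp3 (adjusted p = 0.022) and 1700009P17Rik (now Cfap126; 0.024) passed as well. The GFP-negative level of Foxj1 was highest in line SN2286, at 10.6 CPM, and without that library its log2 fold change was −2.54. Of 5 measured neuroendocrine genes 3 fell and 1 rose (1 and 3 adjusted over the list alone; set test adjusted p = 0.22), with Cplx2 (−1.93) and Nov (−2.84) lower and Uchl1 (1.27) higher. Of 3 measured gastric and intestinal genes only Krt20 passed, falling (−2.23; set test adjusted p = 0.27). With line as a term Anxa10 fell too (adjusted p = 0.021), as it did without the GFP-positive library of line SN2286 (0.012). Of 4 measured mesothelial genes Bnc1, at 0.162 ± 0.158 against 14.7 ± 0.354 CPM, and Upk1b (−5.77, and −6.46 without the GFP-positive library of line SN2285) fell, and Krt19 (adjusted p = 0.072; 0.0054 with line as a term, and 0.024 and 0.049 without the GFP-negative library of line SN2286 or SN2294) and Msln (0.85) did not pass. The mesothelial list did not pass the set test (adjusted p = 0.060), but did without the GFP-positive library of line SN2285 (adjusted p = 0.043) or SN2293 (0.039) or the GFP-negative library of line SN2286 (0.019) or SN2294 (0.0495). Of 4 measured endothelial genes Esam rose (log2 fold change 3.84, SE 0.32, adjusted p = 4.4e-05) and Plvap fell (log2 fold change −0.83, SE 0.29, adjusted p = 0.041; set test adjusted p = 0.59), and the list's median (−0.25) and mean (0.63) differed in sign. The call of Plvap was lost without any 1 of 6 libraries, all but the GFP-positive library of line SN2293 and the GFP-negative library of line SN2286, with adjusted p from 0.056 to 0.13. Counts of the vascular genes Pecam1 and Cdh5 were at most 5 and 1 in any library.

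In the set tests, 33 lists were tested together, 15 passed with the preset correlation of 0.01 (6 higher and 9 lower) and 2 passed with the correlation estimated, the fatty acid and surfactant lipid list and the p53 targets. Among the 35 ways of dividing the 8 libraries into groups of 4, 9 called 15 or more lists with the preset correlation, the real one included. The other 8 all kept 3 libraries of 1 sort together, and the 18 divisions with 2 libraries of each sort in both groups called 1 to 11 lists. For 7 of the 15 lists no other division gave as small a p, and these were the AT2, basal, fibroblast, lipid synthesis, epithelial to mesenchymal transition, p53 and Notch lists. For the rest, p was as small in 15 of the 35 divisions for dissociation genes, 12 each for cell cycle and AT1 genes and 8 for club genes. It was as small in 4 each for embryonic progenitor, sterol and Wnt genes and in 3 for MHC class II genes. These counts include the real division, so none can be lower than 1 of 35. Every other division mixes the sorts, which leaves the difference between them inside the groups. The counts therefore do not show how often chance alone would give a list so small a p.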

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

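Of the tests below, those of reads from another library, of depth and of carried basal cells were chosen only after the result was seen; the second macrophage list and the fibroblast comparison were fixed before their values were seen. In each group of 4 libraries, the gap of the highest or lowest library to its nearest neighbour was divided by the range of the group, and a share above Dixon's critical value marked a library as far from the others. Of 365 groups tested 15 passed, against 18.2 that chance alone would give at 1 in 20, and 1 further group of equal values was not tested. Of the 15, 4 concerned the GFP-negative and 3 the GFP-positive library of line SN2294.

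The GFP-negative library of line SN2294 stood apart in depth, at 5910344 counts where the others had at least 14408203 (share 0.879). It was also highest in the mean log2 CPM of the measured macrophage and leukocyte genes (4.39 against 2.08 to 2.21; share 0.943) and in Coro1a (3.24 against −0.53 to 0.01; share 0.855).

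Leukocyte transcripts were thus high in 1 of the 4 GFP-negative libraries, where the list without Cd68 summed to 93.6 CPM. Reads carried over from another library of the series are argued against, since the highest sum in any other library was 2.43 CPM, and so is low depth, since the raw count there was 594 against 13 to 40 in the 3 deeper GFP-negative libraries. A second list of 25 macrophage genes, 5 of them at 1 CPM or more in each of the other 3 GFP-negative libraries and none in another list, had 21 members with at least 10 counts. These had a median log2 ratio of 2.28 to the other 3 (quartiles 1.31 to 3.40), and 19 of the 21 were highest there, which is consistent with macrophages in that sort; the most abundant were Apoe (364 CPM), Lgmn (236), Cd14 (160), Lcp1 (63.2), Plek (37.3) and Ctss (26.6), of which Cd14 (log2 ratio −0.18) and Lcp1 (0.95) were higher in other libraries. The labels name only a GFP gate, which would not remove GFP-negative leukocytes, and no other biological explanation was tested.

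Basal transcripts remained in the GFP-positive libraries, with Trp63 furthest from the others in line SN2285 (log2 CPM 2.60 against 1.53 to 1.61; share 0.925). Cells of the GFP-negative sort carried into the GFP-positive sort would give all basal genes of a line 1 ratio. The quartiles of the ratios of 14 genes lay 2.69-fold, 4.26-fold, 5.70-fold and 3.90-fold apart in lines SN2285, SN2286, SN2293 and SN2294, while the lines ranked alike across genes beyond chance (Kendall's W 0.242, permutation p = 0.01). For most of these genes, carried cells and low expression in the GFP-positive cells therefore cannot be told apart. Itgb4 (8.40 to 11.5%), Cdh3 (14.5 to 23.0%) and Lamb3 (52.8 to 89.5%) had the highest ratios in all 4 lines, where the median was 1.34 to 3.80%. For these genes, picked for their high ratios, the values argue against carried cells of the average GFP-negative kind as the whole source. The median ratio of fibroblast genes was 1.37 to 1.76 times that of basal genes in the 4 lines, consistent with carried cells that are a random sample of the GFP-negative sort. No biological explanation was tested.

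The other results are given as values, in log2 CPM. Among GFP-negative libraries, Foxa1 was 8.22 in line SN2286 against 7.92 to 7.94 (share 0.950), and Herpud1 was 7.25 in the same line against 6.74 to 6.82 (0.860). Ldhb was 6.16 in line SN2293 against 6.31 to 6.34 (0.832). Cplx2 was 3.31 in line SN2285 against 2.78 to 2.86 (0.847), and Pcna was 7.13 there against 7.28 to 7.31 (0.833). Krt20 was 2.09 in line SN2294 against 2.83 to 2.91 (0.906). Among GFP-positive libraries, 1810011O10Rik was −0.31 in line SN2294 against 0.90 to 1.12 (0.851), Hdc was 7.54 there against 6.53 to 6.69 (0.834), and the mean of the embryonic progenitor list was 2.44 against 2.73 to 2.76 (0.901). Clu was 14.56 in line SN2285 against 14.30 to 14.34 (0.830), and Apcdd1 was 0.45 in line SN2293 against at least 1.09 (0.849).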

How the results depend on the processing

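Thinning to a common depth was the only alternative chosen after seeing the data. With each library left out in turn, 4535 to 5135 genes passed (2067 to 2368 higher, 2468 to 2767 lower), 1953 to 2090 of them at least 2-fold (524 to 625 higher, 1382 to 1523 lower), 16 to 18 lists passed, and the log2 fold change of Sftpc was 4.12 to 4.58. Over 15 other settings 4443 to 6321 genes passed, 1659 to 2408 of them at least 2-fold, and Sftpc stayed past the threshold at 4.19 to 4.76 (highest adjusted p = 0.022). Thinning every library to the depth of the shallowest gave the lowest count, 4443 in place of 5231, so that depth limits how many genes pass. Scaling by library size alone gave 1505 genes higher in GFP-positive cells, since it lowered the median of all genes by 0.15 relative to the TMM fit (from −0.01 to −0.16). The DESeq2 Wald test shared 5170 of the 5231 calls. No named gene called with all libraries changed sign under these settings; some without a call did, such as Coro1a (−1.57 to 0.65).

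Of the lists, 2 passed with an estimated correlation in place of 15, and 21 passed with fry, which does not compare a list with other genes. The estimates were 0.0012 (lipid synthesis) and 0.0041 (p53 targets) for the 2 kept and 0.016 to 0.67 for the 13 lost, where the preset was 0.01. For the 2 kept the unadjusted camera p also rose, from 1.6e-09 to 5.4e-04 and from 3.8e-08 to 0.0011. A higher correlation therefore does not account for all of the change, and the rest was not tested. Without a filter the sort accounted for 67.4% of the sum of squares in place of 79.0%, and 85.9% without line SN2294. Both moved by more than the SD of this share over the 4 fits that leave out a line (3.02), and the cause was not tested. The fit without line SN2294 is 1 of those 4, and the 4 share libraries, so this SD is not a spread between lines. For lists not called, no filter gave the neuroendocrine (adjusted p = 0.031), mesothelial (0.047), ciliated (0.047), hypoxia (0.047) and lung transcription factor (0.013) lists, and library size alone gave the latter 2 lists (0.016 and 0.017). The 33 lists gave 690 comparisons with an alternative, of which 633 kept their side of the threshold, 18 lost and 39 gained a call. The named genes gave 3337, of which 3257 kept their side, 28 lost and 52 gained a call; the 20 genes highest or lowest by fold kept theirs in all 460. Apart from the results where it is given, line as a term changed no call of a named gene or list.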

Other observations

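The test of AT2 transcripts in this part was chosen only after the result was seen. Of the remaining lists none passed the set test, and several moved both ways. Lysosome and lamellar body genes rose for 9 and fell for 11 of 28 members (9 and 11 adjusted over the list alone; adjusted p = 0.93, limma camera), with the AT2 lamellar body gene Lamp3 higher (2.10) and the saposin precursor gene Psap (−1.26), the cholesterol transfer gene Npc2 (1.52) and the cathepsin gene Ctsc (1.76) beside it; the median lay just under 0 and the mean was 0.24. YAP and TAZ targets rose for 7 and fell for 7 of 20 (7 and 7 adjusted over the list alone; adjusted p = 0.87; median 0.08, mean −0.50), with Crim1 (−1.51), the receptor kinase gene Axl (−4.16), Fjx1 (−4.40) and Wwc1 (1.09) as the named members. Epithelial junction and keratin genes rose for 10 and fell for 7 of 22 (10 and 9 adjusted over the list alone; adjusted p = 0.27), with the claudin gene Cldn3 (1.53) and the protease gene Prss8 (1.13) against the desmosome genes Pkp3 (−1.27) and Dsp (−0.96). EGFR and MAPK output genes rose for 9 and fell for 4 of 20 (9 and 5 adjusted over the list alone; adjusted p = 0.42), 7 fell with line as a term, and with scaling by library size alone 6 rose and 6 fell; the named members were Epha2 (0.83), Etv4 (−0.82), Ier3 (−0.68) and Spred1 (0.49).

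Inflammatory genes of the NF-kB list rose for 6 and fell for 8 of 20 (6 and 9 adjusted over the list alone; adjusted p = 0.76, limma camera), with Icam1 at 1.53, the interleukin antagonist gene Il1rn at −2.59, the complement gene C3 at −1.52 and the chemokine gene Cxcl3 at 3.03. Unfolded protein response genes rose for 5 and fell for 4 of 22 (5 and 4 adjusted over the list alone; adjusted p = 0.58), and with scaling by library size alone 1 rose and 5 fell; the transcription factor gene Xbp1 was at −1.60, Herpud1 at −0.69, Trib3 at 1.07 and Sdf2l1 at 0.47 (adjusted p = 0.0078 by edgeR, and 0.057 with library size alone). Glutathione and NRF2 response genes rose for 6 and fell for 6 of 18 (6 and 6 adjusted over the list alone; adjusted p = 0.93), with Gpx2 (−2.95) and Gsta4 (−1.98) against Gclc (1.46) and Pgd (0.70). Antiprotease and secreted defence genes rose for 3 and fell for 7 of 14 (3 and 7 adjusted over the list alone; adjusted p = 0.58), with the surfactant protein gene Sftpd (1.95) against Ltbp1 (−3.58), and with Slpi (2.01) and Wfdc2 (−1.35).

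Of the 5 genes that differ between the sexes, none passed between the sorts in edgeR, and with line as a term Kdm5d did (adjusted p = 0.035). Xist was at 1104 and 789 CPM in the GFP-positive and GFP-negative libraries of line SN2285 and at 1386 and 961 CPM in those of line SN2286. The Y-linked gene Uty was at 27.5 and 32.7 CPM in line SN2293 and at 27.1 and 24.3 CPM in line SN2294. In lines SN2285 and SN2286 it was at most 0.394 CPM, so that both libraries of every line matched in Uty. By these genes lines SN2285 and SN2286 were female and lines SN2293 and SN2294 male. The lines thus did not all come from the same animal. Xist did not match in line SN2294, at 1.89 CPM in the GFP-positive and 17 CPM in the GFP-negative library, which also held the leukocyte transcripts. The source of this Xist was not tested.

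The AT2 transcripts left in the GFP-negative libraries mostly stood at higher ratios than Sftpc. If GFP-positive cells carried into the GFP-negative sort were their whole source, the members that rose would stand at about the ratio of Sftpc in each line. Their median ratio was 2.44 to 6.07 times that of Sftpc in the 4 lines, and of 24 members 22, 23, 23 and 24 lay above Sftpc, with Napsa below it in lines SN2285, SN2286 and SN2293. This argues against carried cells of the average GFP-positive kind as the whole source. Carried AT2 cells with low Sftpc, and expression of these genes in other cells, stay open, and no biological explanation was tested.

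The 8 libraries can be divided into groups of 4 in 35 ways. The real division called 5231 genes, and 1988 at least 2-fold, where the highest of the others called 5 and 5, so that 1 of 35 was as large in each case. The division with 5 calls set lines SN2285 and SN2286 against lines SN2293 and SN2294. It is also the division of the lines by sex, as the Y-linked genes above show. Its calls are therefore not a measure of chance alone. Every division but the real one mixes the sorts, which leaves the difference between them inside the groups and makes calls unlikely. Among the 8 divisions that part the libraries of every line, the highest of the others called 0. With the pairing by line kept, the count can be no smaller than 1 of 8, so it does not exclude chance. For the lists, 9 of 35 divisions called 15 or more with the preset correlation, and the highest of the others called 18 (16 among those that part every line), so that by this count chance cannot be excluded for the number of lists. The other 8 that called as many are among the 16 that keep 3 libraries of 1 sort together and so retain part of the difference between the sorts (11 to 18 lists), while the 18 with 2 libraries of each sort in both groups called 1 to 11. With an estimated correlation the real division called 2 lists and the highest of the others 0.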
